A study of Homo sapiens with 4 samples.

How the data were processed

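Gene expression was measured on 4 two-colour Agilent whole-genome arrays, each comparing a squamous cell carcinoma line transfected with a microRNA with the same line transfected with a control microRNA. Per the labels, the microRNA-transfected RNA carried Cy5 (red) and the control RNA Cy3 (green) on every array, so no dyes were swapped and a dye effect cannot be separated from the transfection within one microRNA. Total RNA had been extracted with Trizol, per the labels' protocols. SAS and HSC3 received miR-133a, and TE2 and TE13 received miR-145. The labels give the cell line of each array, and the deposited file of the array labelled TE13 carries the line number TE12 in its name; the label was used. Each array was treated as 1 replicate of its microRNA, so the spread within a group is the spread between 2 cell lines, each with its own control.

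The authors deposited scanner output of Agilent Feature Extraction version 10.7.3.1, per the file headers. It holds the mean pixel intensity and the median local background intensity of each spot in both channels, not normalized, together with processed signals that the software had background-subtracted, detrended and dye-normalized within the array with a LOWESS step, per the file headers. The deposited series table holds log10 ratios of Cy5 over Cy3. All of its values (100% in each column) were identical to the log10 ratio column of the scanner output, its column medians were 0, and its direction is therefore the same as that of the scanner files. The probes' positions are those of the files, on the genome build hg17. All 4 arrays lay on 1 slide, so no slide or scan batch could be tested.

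An array held 45015 spots, of which 1639 were control spots, and 41000 different probes, 264 of them printed 10 times. The mean signals were background-corrected with the normexp method of limma (version 3.58.1 in R 4.3.3) with an offset of 50, turned into log2 ratios of red over green, and normalized within each array by loess, with control spots at weight 0. Spots marked as non-uniformity or population outliers in either channel (163 to 234 per array) were left out, no spot was saturated, and spots of one probe were averaged. No normalization between arrays was applied. Probes were named through their RefSeq accession in a table of the GRCh38.p14 assembly, used for names only. That matched 23434 probes, and the other 17566 kept the name in the files. A probe was used if it was well above background in at least 1 channel on both arrays of at least 1 microRNA, and if it had a value on all 4 arrays. This left 28911 probes and removed 12089. Each gene was represented by its probe of highest mean intensity, which gave 21698 genes, a number that includes unnamed transcripts.

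The precision is limited by the number of arrays. On each array 68.4% to 72.5% of non-control spots were well above background in red and 66.5% to 69.6% in green. Spots of the same probe printed 10 times on an array had a median SD of 0.025 to 0.031 log2 units. The 10 spike-in probes had log2 ratios whose SD over the 4 arrays was 0.094 at the median and 0.165 at most.

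Differences were tested with limma (lmFit and eBayes) on all 4 arrays, with 1 coefficient per microRNA tested against 0, and with the difference of the coefficients as a contrast. The fit had 2 residual degrees of freedom, or 4.44 after moderation. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. As a description without a test, genes were counted that were lower or higher by 2-fold or more in both lines of a microRNA, beside the count that independent lists of these sizes would share. For 24 gene lists, camera with a preset correlation of 0.01 compared the list's genes with all other genes, adjusted over the lists of a comparison, and camera with an estimated correlation was run beside it. The run with an estimated correlation also rests on the 2 residual degrees of freedom of the fit. A call lost there therefore does not show that the genes of a list were correlated. Lists with under 5 measured genes were not to be tested, and all 24 had more. The median of each list on each array was placed among 10000 random lists of the same size matched on mean intensity. The lists were reported miR-133a targets, reported miR-145 targets, actin cytoskeleton, cell adhesion and integrins, S phase and replication, G2 and mitosis, interferon-stimulated genes, inflammatory cytokines and NF-kB targets, p53 targets, endoplasmic reticulum stress and ATF4 targets, hypoxia and glycolysis, cholesterol synthesis, squamous differentiation and cornified envelope, basal epithelial markers, mesenchymal and matrix genes, TGF-beta and YAP-responsive genes, EGFR and MAPK pathway and feedback, small RNA machinery, cytosolic ribosomal proteins, oxidative phosphorylation, striated and smooth muscle markers, fibroblast markers, leukocyte and endothelial markers, and replication-dependent histones.

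Genes named in the text followed a rule set before the data were examined, as were the groups, the tests and the lists. For each microRNA the rule took the 10 lowest and 10 highest genes by the ratio of the line that changed less, among named genes well above background in at least 1 channel on both arrays and changed in the same direction in both lines, without Y-linked genes or names of clones and open reading frames. For the difference it took the 5 genes in each direction with the widest gap between the nearest arrays of the microRNAs. FSCN1 was named throughout, and up to 4 members with the largest mean change were named for each list. Where a probe was not well above background in 1 channel on both arrays of a microRNA, the fold is given as a bound against the lowest signal well above background in that channel, after loess and quantile normalization of mean intensities between arrays, and is open to dye bias.

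The gene test was tested on simulated log2 ratios of the 21698 genes for the miR-133a comparison. Each gene had its spread pooled over both microRNAs, used alike on all 4 arrays. The measured ratios were wider with miR-133a than with miR-145, which the simulation did not copy, so its false calls do not carry over to the measured arrays. Of 200 genes changed by 2 log2 units, 72% were recovered with 3 false calls, and of 200 genes changed by 3 log2 units, 81.5% with 4 false calls. None of 200 genes changed by 1 log2 unit was recovered with these spreads. When all genes had the same spread, all 200 genes changed by 1 log2 unit were recovered with 12 false calls. The list test called a list of 40 genes shifted by 0.25 log2 units in 50 of 50 simulations of that comparison and an unshifted list in 0 of 50. The simulated genes were independent and the lists random. These simulations therefore do not cover lists of correlated genes, such as G2 and mitosis with an estimated correlation of 0.98.

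Alternatives were no background subtraction, Agilent's processed signals, median centring in place of loess, the series table's values, no filter on dim probes, a filter that required both channels on all 4 arrays, the mean of all probes of a gene, outlier spots kept, an intensity trend in the prior variance, a fit of the 2 arrays of a microRNA alone, each array left out in turn, a 1.5-fold size rule, and the estimated correlation in camera. The comparison of genes with and without a seed match in their 3' UTR was not analysed here, because no 3' UTR sequence was used here. A list of SRF target genes, 2 tests in the closing section, the way list values are compared between alternatives and the use of mean log2 intensity for the trend were chosen after the values were seen. Python 3.11.15 and matplotlib 3.10.9 drew the figures.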

Results

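The series measured which mRNAs changed when miR-133a or miR-145 was put into squamous cell carcinoma lines, as a search for target genes of these microRNAs. SAS and HSC3, lines from oral squamous carcinoma, received miR-133a, and TE2 and TE13, lines from oesophageal squamous carcinoma, received miR-145. RNA was taken at 72 h, and each of the 4 arrays set a transfected line against the same line with a control microRNA, so each microRNA had 2 replicates, both different lines. Between 66.5% and 72.5% of spots were well above background in each colour, and 21698 genes were tested. The spread of the log2 ratios was wider with miR-133a (SD 0.56 in SAS and 0.82 in HSC3) than with miR-145 (SD 0.30 in TE2 and 0.38 in TE13). Across genes, which are not independent replicates, the log2 ratios of SAS and HSC3 correlated with r = 0.66 and those of TE2 and TE13 with r = 0.51, against 0.09 to 0.21 for arrays of different microRNAs. All p-values rest on 2 lines per microRNA, the labels do not say more about separate cultures, and a dye effect is part of each ratio.

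**Figure D1:**
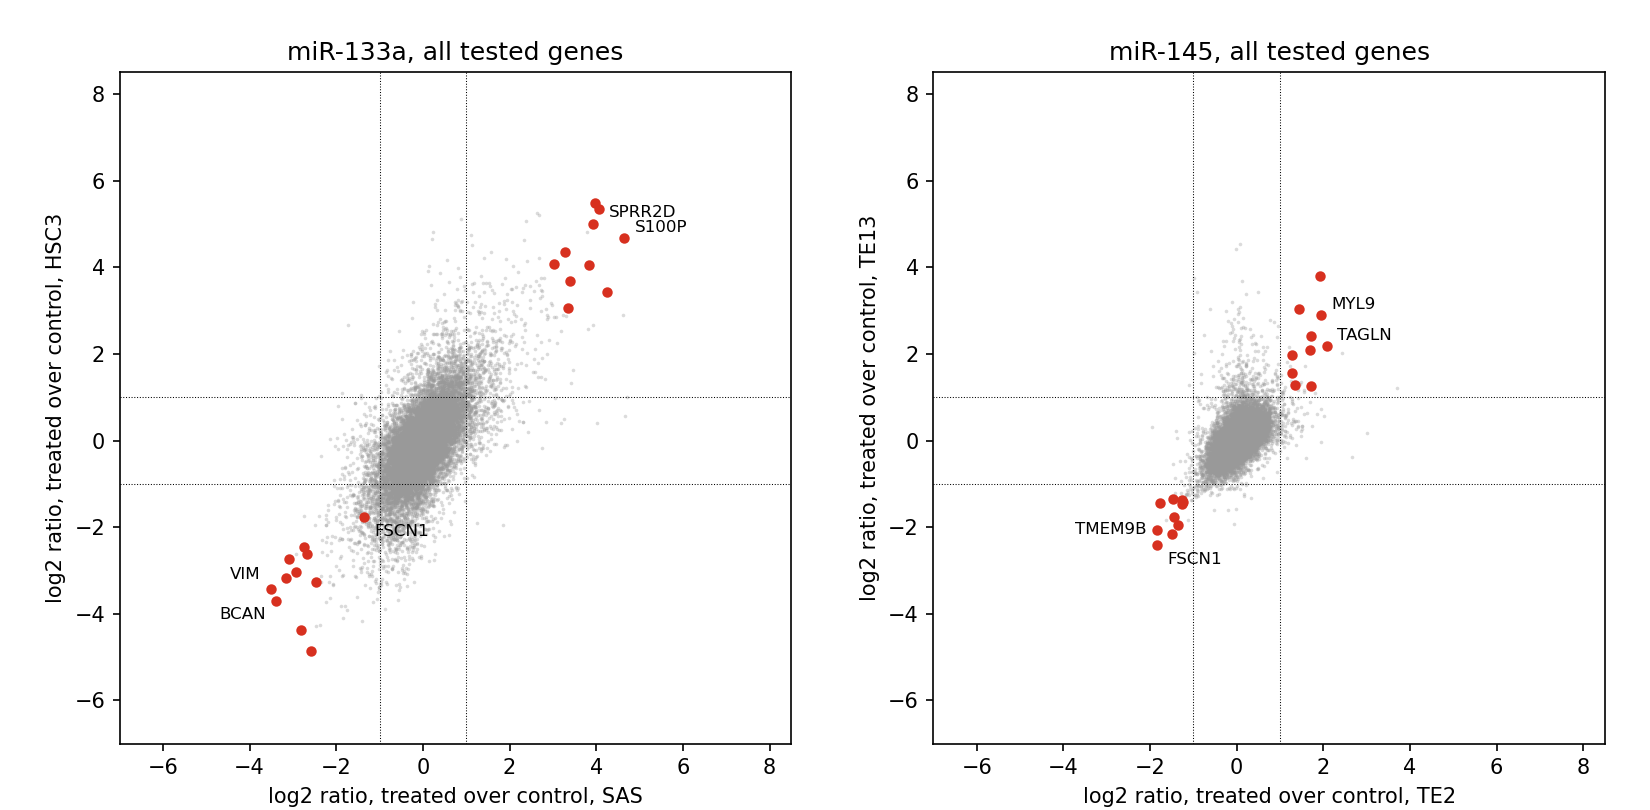
Each point is 1 of the 21698 genes, with its log2 ratio (treated over control) in the first line of a microRNA on the x axis and in the second line on the y axis, miR-133a on the left and miR-145 on the right. Red points are the genes named by rule and FSCN1, which lay at -1.35 in SAS, -1.77 in HSC3, -1.84 in TE2 and -2.42 in TE13; dotted lines mark 2-fold.

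The miR-133a comparison asked which genes that microRNA changed in the oral lines. Several genes of actin filaments were among the most reduced, and several of the cornified envelope, the outer shell of terminally differentiated squamous cells, among the most increased. VIM, the intermediate filament vimentin, fell by 3.51 log2 units in SAS and 3.43 in HSC3, a mean of -3.47 (11.1-fold, SD 0.059, n = 2). Its probe lies on chromosome 10 at 17318353 to 17319262 of hg17. TPM1 (-3.17) and TPM2 (-2.65), tropomyosins that run along actin filaments, fell in both lines, as did TAGLN2 (-2.61), an actin-binding transgelin, and CAV1 (-3.73), the coat protein of caveolae. The other 5 lowest genes by the rule were LHFPL6 (-3.59), BCAN (-3.54), DYNLT2B (-2.98), BACE1 (-2.91) and IKBIP (-2.87).
BCAN had another probe at 0.08, and 1 of the 5 other probes of TPM1 moved the other way (2.36), so both values depend on the probe. A second probe moved the same way but less for TPM2 (-0.94), IKBIP (-1.03), CRCT1 (2.498) and KRT80 (2.06), and tropomyosin genes are near-identical in parts of their sequence.

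The 10 highest genes under miR-133a rose by 3.20 to 4.73 log2 units. S100P, a calcium-binding protein, rose by 4.65 in SAS and 4.66 in HSC3, which is 25.2-fold (SD 0.012, n = 2), with its probe on chromosome 4 at 6816891 to 6816950. SPRR2C (4.73) and SPRR2D (4.70), small proline-rich proteins of the cornified envelope, rose with CRCT1 (4.47), KRT80 (3.94) and KRT6C (3.20), the last 2 of them keratins. The remaining ones were IL1R2 (3.83), a decoy receptor for interleukin 1, DEFB103B (3.82), an antimicrobial defensin, NFE2 (3.54) and HSPB8 (3.54), a small heat shock protein. Members of the SPRR2, KRT6 and DEFB103 families are so alike that these probes may not tell them apart. All 20 genes passed the limma threshold, at adjusted p = 0.0215 to 0.0357.

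With limma 2518 genes passed under miR-133a, 1232 higher and 1286 lower. An unadjusted p under 0.05 was found for 7786, where 1085 would be expected by chance if both microRNAs had the same spread. The fit pools each gene's spread over both, and the log2 ratios were wider with miR-133a than with miR-145. The standard errors under miR-133a may therefore be too small, and 1085 too low as the number expected by chance. The 2518 calls, which include the 20 named genes, may then hold more false ones than the threshold allows. These calls depended on the miR-145 arrays in the fit. With the miR-133a arrays alone the count was 0, 5077 genes had an unadjusted p under 0.05 and none of the 20 named genes passed. Leaving out TE2 or TE13 gives that same fit, because a lone array of a microRNA adds nothing to the measured spread. The count was 6568 with median centring in place of loess, where the even split was lost, with 5639 higher and 929 lower. By size alone, 452 genes were lower by 2-fold or more in both lines and 501 were higher, where independent lists of these sizes would share 64.7 and 59.9. These counts and their balance depended on the scaling, with 193 lower and 1572 higher with median centring, and 919 lower and 969 higher with Agilent's processed signals or the series table.

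FSCN1, the actin-bundling protein fascin, is the gene on which work on these microRNAs in squamous carcinoma has centred, and since it may have been picked from these arrays it is not taken as independent evidence. Under miR-133a it fell by 1.35 in SAS and 1.77 in HSC3, a mean of -1.56 (2.95-fold, SE 0.20, limma adjusted p = 0.0291). Its probe lies on chromosome 7 at 5418183 to 5418242 of hg17, and a second probe at 5416881 to 5418181 gave -1.41 and -1.81. The call was lost with the miR-133a arrays alone, at a limma adjusted p of 0.139 (SE 0.19). Leaving out TE2 or TE13 gives that same fit.

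**Figure D2:**
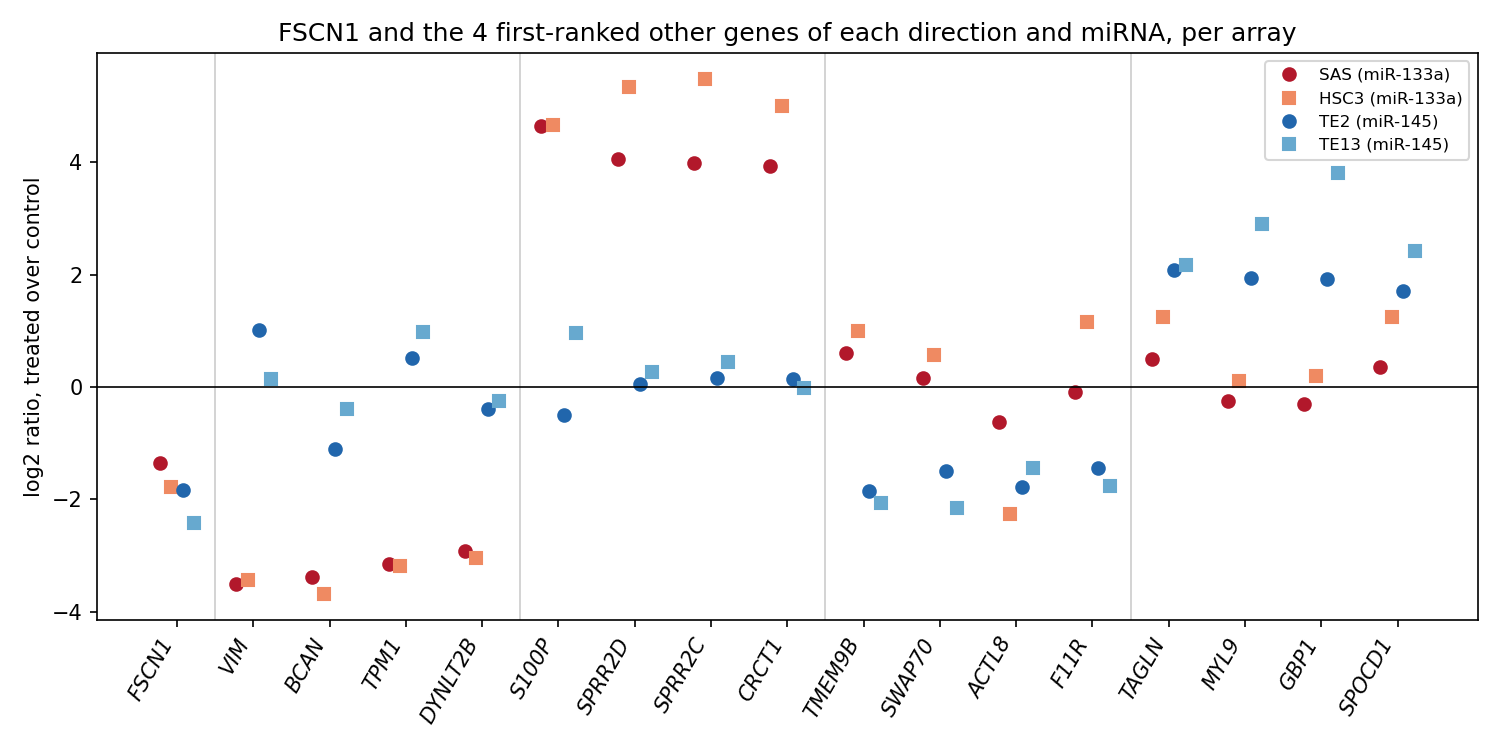
The y axis gives the log2 ratio (treated over control) of FSCN1 and of the 4 first-ranked other genes in each direction for each microRNA, with 1 point per array. FSCN1 lies below 0 on all 4 arrays, while S100P lies near 4.65 in both miR-133a lines and at -0.50 and 0.96 in the miR-145 lines; ACTL8 was not well above background in the miR-145-treated channel.

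Squamous differentiation and cornified envelope genes rose as a list under miR-133a, with a median of 1.46 over 34 genes (camera adjusted p = 6.75e-09, but adjusted p = 0.655 with an estimated correlation). Of these 34 genes, 12 rose, 0 fell and 22 did not pass, and 23 rose when adjusted over the list alone. Beside SPRR2D, the largest were GRHL3 (3.94) and OVOL1 (3.45), transcription factors of epidermal differentiation, and PI3 (3.30), the protease inhibitor elafin. Basal epithelial markers fell as a list, with a median of -0.30 over 17 genes (camera adjusted p = 0.0488, and adjusted p = 0.655 with an estimated correlation). Among them 5 fell and 0 rose, and 5 fell when adjusted over the list alone, with TP63 (-2.89), the transcription factor of basal cells, DST (-2.83) and ITGB4 (-1.17) lower, while KRT15 (1.06) did not pass. With median centring the list's mean relative to all genes went from -0.48 to -0.09 (camera adjusted p = 0.945). Its call was also lost without SAS (camera adjusted p = 0.0938), without either TE2 or TE13 (0.0600) and with Agilent's processed signals (0.0549), although the mean relative to all genes was no smaller there, at -0.53, -0.48 and -0.53.

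Actin cytoskeleton genes fell as a list under miR-133a, with a median of -0.46 over 48 genes (camera adjusted p = 9.46e-05, and adjusted p = 0.655 with an estimated correlation). Of the 48 genes 15 fell, 3 rose and 30 did not pass, and 24 fell and 5 rose when adjusted over the list alone. TPM1, TPM2, TAGLN2 and TPM4 (-2.30) were lowest. With median centring, which left the median of all genes at 0.238, the list passed no longer (camera adjusted p = 0.119), at a mean relative to all genes of -0.27 against -0.62. Reported miR-133a targets fell too, with a median of -0.57 over 33 genes (camera adjusted p = 9.46e-05, and adjusted p = 0.655 with an estimated correlation). Of these, 12 fell, 1 rose and 20 did not pass, and 17 fell and 3 rose when adjusted over the list alone, with CAV1, TAGLN2, TPM4 and ARPC5 (-2.24), a subunit of the actin-nucleating Arp2/3 complex, lowest. Part of that list may have been chosen on these samples, so its direction is not taken as independent evidence. The actin list shares members with it, among them FSCN1, TAGLN2, TPM4 and ARPC5, so the falls of the lists are not independent of each other. Reported miR-145 targets did not pass under miR-133a (camera adjusted p = 0.0707, but 0.0428 with no filter on dim probes, at a mean relative to all genes of -0.22 against -0.21), with 8 of 52 genes lower, 2 higher and 42 not past, and 11 lower and 2 higher when adjusted over the list alone.

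Cell cycle genes were lower under miR-133a, far more in HSC3 than in SAS. The G2 and mitosis list had a median of -0.47 in SAS and -2.48 in HSC3, and fell as a list (camera adjusted p = 9.56e-09, and adjusted p = 0.655 with an estimated correlation). None of its 40 genes passed by limma, over all genes or adjusted over the list alone, although 37 were below 0 in both lines, with CDCA8 (-2.44), CENPF (-2.39), CENPA (-2.31) and TOP2A (-2.27) lowest. The S phase and replication list had a median of -0.31 in SAS and -1.95 in HSC3 and also fell (camera adjusted p = 9.91e-08, and adjusted p = 0.655 with an estimated correlation). Of its 40 genes 3 fell, 0 rose and 37 did not pass, and 7 fell when adjusted over the list alone. CDT1 (-2.05), which licenses replication origins, and RFC5 (-1.77), a clamp loader subunit, fell, while DTL (-2.15) and RFC4 (-1.80) did not pass.

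Defence genes were higher under miR-133a. Interferon-stimulated genes had a median of 0.75 over 41 genes (camera adjusted p = 0.00306, and adjusted p = 0.703 with an estimated correlation). None of the 41 passed by limma, over all genes or adjusted over the list alone, with OASL (8.59-fold), IFIT1 (2.34), RIGI (2.05) and SAMD9L (2.03) highest. Inflammatory cytokines and NF-kB targets had a median of 0.86 over 36 genes (camera adjusted p = 0.00714, and adjusted p = 0.703 with an estimated correlation). Among these 3 rose, 0 fell and 33 did not pass, and 3 rose when adjusted over the list alone, while the largest, LCN2 (2.99), SAA1 (2.77), SAA2 (2.71) and C3 (2.57), did not pass. Without HSC3 neither list passed (camera adjusted p = 0.0995 and 0.542), at means relative to all genes of 0.60 against 0.79 and 0.23 against 0.97. With median centring both lost their calls (camera adjusted p = 0.119 for both), although their means relative to all genes were no smaller, at 0.83 and 1.05.

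Smaller shifts were found in 3 further lists under miR-133a. Endoplasmic reticulum stress and ATF4 targets had a median of -0.31, with 4 of 30 genes lower and 0 higher, and 4 lower when adjusted over the list alone, but their mean relative to all genes turned positive (0.011) with median centring. The camera adjusted p was 0.0231, and adjusted p = 0.671 with an estimated correlation. Without HSC3 the mean relative to all genes was only -0.08 against -0.33. DDIT4 (-1.22) fell, while CTH (-1.42), SLC7A11 (-1.14) and HERPUD1 (-1.09) did not pass. Cholesterol synthesis genes had a median of -0.16, with 4 of 25 genes lower and 0 higher, and 4 lower when adjusted over the list alone, among them SQLE (-1.85) and MVK (-1.03), enzymes of the pathway, and the list's mean too turned positive (0.0078) with median centring. The camera adjusted p was 0.0231, and adjusted p = 0.655 with an estimated correlation. Without SAS it was 0.428, at a mean relative to all genes of -0.11 against -0.28, and it was 0.0600 with Agilent's processed signals and 0.0545 with the series table, at means hardly changed (-0.27 for both). Cytosolic ribosomal protein genes had a median of 0.24, with 3 of 41 genes higher (RPS25 0.89, RPL38 0.72 and RPL23 0.64), 0 lower, and 0 when adjusted over the list alone. The camera adjusted p was 0.00289, and adjusted p = 0.655 with an estimated correlation, and it was 0.0779 without SAS, 0.559 with Agilent's processed signals and 0.575 with the series table. The mean relative to all genes was 0.22, and there 0.19, 0.05 and 0.04.

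The other lists did not pass under miR-133a. The camera adjusted p was 0.961 for cell adhesion and integrins (1 gene higher, 6 lower of 38), 0.318 for p53 targets (3 higher, 0 lower of 29) and 0.0748 for hypoxia and glycolysis (1 higher, 3 lower of 31). It was 0.675 for mesenchymal and matrix genes (2 higher, 2 lower of 32), 0.630 for TGF-beta and YAP-responsive genes (3 higher, 3 lower of 26), and 0.961 for EGFR and MAPK pathway and feedback (3 higher, 5 lower of 34). It was 0.587 for small RNA machinery, 0.358 for oxidative phosphorylation, 0.210 for striated and smooth muscle markers, 0.318 for fibroblast markers, 0.243 for leukocyte and endothelial markers and 0.0556 for replication-dependent histones. Adjusted over the list alone, the counts were 2 higher and 7 lower for cell adhesion, 7 and 6 for p53 targets, 1 and 3 for hypoxia, 2 and 2 for mesenchymal genes, 4 and 5 for TGF-beta and YAP, and 9 and 7 for EGFR and MAPK. The test pointed down for cell adhesion although median and mean were above 0, and up for EGFR and MAPK although the median was -0.0074. The histone list was higher at camera adjusted p = 0.00342 without SAS and 0.0374 without TE2 or TE13, and oxidative phosphorylation at 4.52e-05 with median centring. The histone list also passed with the mean of all probes (0.0440), with no filter on dim probes (0.0428) and with probes above background in both channels (0.0486), and the hypoxia list was lower with no filter on dim probes (0.0299).

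The miR-145 comparison asked the same of the oesophageal lines, where the changes were smaller. FSCN1 was at -1.84 in TE2 and -2.42 in TE13, a mean of -2.13 (4.37-fold lower, SE 0.20, limma adjusted p = 0.330), and its second probe at -2.03 and -2.62. TMEM9B had a mean of -1.95, with its probe on chromosome 11 at 8925479 to 8925538. SWAP70, an exchange factor for Rac, was at -1.82 (its other probe at -0.19), and F11R, a junctional adhesion molecule, at -1.61. ALDH3A1 (-1.65) and AKR1B10 (-1.31), enzymes that detoxify aldehydes, GMFB (-1.42), JADE1 (-1.37) and APH1A (-1.33), a subunit of gamma-secretase, were the other low genes, with ACTL8, which was at least 2.91-fold lower. The highest genes were TAGLN (2.13) and MYL9 (2.42), contractile proteins typical of smooth muscle, GBP1 (2.86), an interferon-induced GTPase, SPOCD1 (2.06), GLIPR1 (1.90) and IL6 (2.24), a cytokine. ATF3 (1.42), a stress-induced transcription factor, ROR1 (1.31, with the control channel well above background on 1 of 2 arrays), PTGER4 (1.63), a prostaglandin receptor, and FN1 (1.48), fibronectin, completed the 10. A second probe gave smaller means for GMFB (-0.83), GLIPR1 (0.97), ATF3 (0.57), ROR1 (0.46), PTGER4 (0.66) and FN1 (0.71), so their sizes depend on the probe.

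None of these 20 genes passed, at limma adjusted p = 0.330 to 0.460. With limma 0 genes passed under miR-145, and 2650 had an unadjusted p under 0.05, where 1085 would be expected by chance. That fit takes 1 spread per gene from all 4 arrays, and the log2 ratios were wider with miR-133a. With the miR-145 arrays alone 0 genes passed as well, but 5235 had an unadjusted p under 0.05. FSCN1 then had an SE of 0.16 and a limma adjusted p of 0.0717. By size alone, 29 genes were lower by 2-fold or more in both lines and 34 were higher, where independent lists would share 0.26 and 1.99. These counts too depended on the scaling, with 7 lower and 171 higher with median centring, and 62 lower and 135 higher with Agilent's processed signals or the series table. The pairs of arrays of different microRNAs, with longer lists, shared 10 to 23 lower genes (1.97 to 8.53 expected) and 20 to 107 higher genes (4.5 to 26.5 expected).

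Over all genes, 0 members of any list passed by limma under miR-145. Interferon-stimulated genes were higher as a list, with a median of 0.72 (camera adjusted p = 7.23e-06, and adjusted p = 0.734 with an estimated correlation). That rested on TE13, where the median was 1.505 against -0.08 in TE2, and without TE13 the list's mean relative to all genes was -0.17 (camera adjusted p = 0.0328). GBP1, RSAD2 (2.31), MX2 (1.57) and ISG20 (1.54) were highest, and 0 of 41 passed adjusted over the list alone. Inflammatory cytokines and NF-kB targets were higher with a median of 0.53 (camera adjusted p = 0.000476, and adjusted p = 0.734 with an estimated correlation), but without TE13 the mean relative to all genes was 0.07 against 0.61 (camera adjusted p = 0.627). IL6, CXCL11 (2.20), CCL5 (1.38) and TNFAIP3 (1.36) led that list, of which 0 of 36 passed adjusted over the list alone.

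Actin cytoskeleton genes were higher as a list under miR-145, with a median of 0.18 over 48 genes (camera adjusted p = 0.0161, and adjusted p = 0.654 with an estimated correlation). Adjusted over the list alone, 11 were higher and 4 lower, with MYL9, TAGLN and LIMA1 (1.32) highest and FSCN1 lowest. With the mean of all probes the camera adjusted p was 0.0518, at a mean relative to all genes of 0.17 against 0.21. Reported miR-145 targets were lower by the test, with a median of -0.05 over 52 genes (camera adjusted p = 0.0456, and adjusted p = 0.547 with an estimated correlation). Their median was -0.05 in TE2 and 0.04 in TE13, and 22 members were below 0 in both lines and 22 above 0 in both. Adjusted over the list alone 8 were lower and 1 higher, with FSCN1, SWAP70, F11R and PODXL (-1.09) lowest, though PODXL did not pass. Part of that list too may have been chosen on these samples and is not taken as independent evidence. Its call was lost without TE2 (camera adjusted p = 0.138) or without either SAS or HSC3 (0.120), nor with Agilent's processed signals (0.0877), the series table (0.0892), the mean of all probes (0.0946) or no filter on dim probes (0.0775). The mean relative to all genes moved little there, as it was -0.18 at first and unchanged without SAS or HSC3, -0.19 with processed signals and the series table, and -0.16 in the other 3. Reported miR-133a targets did not pass under miR-145 (camera adjusted p = 0.403), with 1 higher and 1 lower adjusted over the list alone.

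Mesenchymal and matrix genes were higher as a list under miR-145, with a median of 0.27 (camera adjusted p = 0.0313, and adjusted p = 0.547 with an estimated correlation), with the call lost without TE13 (0.0928) and with no filter on dim probes (0.0810), at means relative to all genes of 0.19 and 0.16 against 0.24. FN1 was the 1 gene past adjusted over the list alone, and COL4A1 (1.36), MMP1 (-1.21) and COL4A2 (1.07) had the next largest means. TGF-beta and YAP-responsive genes were higher with a median of 0.25 (camera adjusted p = 0.0279, and adjusted p = 0.547 with an estimated correlation), with the call lost without TE2 (0.0540), where the mean relative to all genes was still 0.22 against 0.26. INHBA (1.19) and AMOTL2 (0.95) were the 2 genes past adjusted over the list alone, and CCN1 (0.85) and THBS1 (0.72) came next. EGFR and MAPK pathway and feedback genes were higher with a median of 0.30 (camera adjusted p = 0.00203, and adjusted p = 0.547 with an estimated correlation). DUSP5 (1.21) and DUSP1 (0.92), phosphatases that damp MAPK signals, and EREG (1.01) and AREG (0.94), ligands of EGFR, had the largest means, and 0 passed adjusted over the list alone.

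Cytosolic ribosomal protein genes were higher under miR-145 with a median of 0.24 (camera adjusted p = 1.82e-05, and adjusted p = 0.547 with an estimated correlation), and 0 passed adjusted over the list alone. With Agilent's processed signals (0.159) or the series table (0.165) the mean relative to all genes was 0.05 and 0.04 against 0.17. RPL35 (0.62), RPL23 (0.54), RPS27 (0.51) and RPL38 (0.50) were highest. Oxidative phosphorylation genes were lower with a median of -0.14 (camera adjusted p = 0.000476, and adjusted p = 0.654 with an estimated correlation), but higher with median centring, at a mean of 0.13 relative to all genes. COXFA4 (-1.12) was the 1 gene past adjusted over the list alone, before SDHC (-0.54), NDUFB5 (-0.43) and ATP5F1C (-0.41). Cholesterol synthesis genes were lower with a median of -0.16 (camera adjusted p = 0.0367, and adjusted p = 0.734 with an estimated correlation), but hardly so without TE2, where the mean relative to all genes was -0.03 against -0.14 (camera adjusted p = 0.888), and slightly higher with median centring (0.050). The call was also lost with processed signals (0.119), the series table (0.120), the mean of all probes (0.0518) or probes above background in both channels (0.0515), although the mean relative to all genes was nearly the same there (-0.14, -0.14, -0.14 and -0.13). MVD (-0.61), PMVK (-0.49) and DHCR7 (0.48) were among the members with the largest means, and 0 passed adjusted over the list alone. Replication-dependent histones, which are near-identical genes, were lower with a median of -0.12 (camera adjusted p = 0.0313, and adjusted p = 0.734 with an estimated correlation), but less so without TE2 (0.528), where the mean relative to all genes was -0.13 against -0.25. The histone call was also lost with processed signals (0.0619), the series table (0.0593) and the mean of all probes (0.0518), at means of -0.28, -0.28 and -0.23. H1-3 (-0.76), H3C4 (-0.61), HIST1H2BD (-0.57) and H3C10 (-0.52) were lowest, and 0 passed adjusted over the list alone. With median centring the histone (camera adjusted p = 0.134), mesenchymal (0.953), TGF-beta and YAP (0.189), inflammatory (0.0639) and miR-145 target (0.0926) lists lost their calls under miR-145. Their means relative to all genes were then -0.12, 0.18, 0.28, 0.62 and -0.11, against -0.25, 0.24, 0.26, 0.61 and -0.18, so those of TGF-beta and YAP and of inflammatory genes were no smaller.

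The other lists did not pass under miR-145. The camera adjusted p was 0.575 for cell adhesion and integrins, 0.0752 for S phase and replication, 0.0683 for G2 and mitosis, 0.730 for p53 targets, 0.115 for endoplasmic reticulum stress and ATF4 targets and 0.125 for hypoxia and glycolysis. It was 0.528 for squamous differentiation and cornified envelope, 0.567 for basal epithelial markers, 0.394 for small RNA machinery, 0.881 for striated and smooth muscle markers, 0.201 for fibroblast markers and 0.138 for leukocyte and endothelial markers. ATF3, of the endoplasmic reticulum stress list, was the 1 gene of these lists past adjusted over the list alone. The test pointed down for cell adhesion although median and mean were above 0, for p53 targets although the mean was above 0, and for the squamous and muscle lists although the median was above 0. Leaving out SAS or HSC3 changes only the spread that the test uses under miR-145. The means relative to all genes stayed at -0.25 for G2 and mitosis and -0.17 for S phase. The G2 and mitosis mean was -0.45 without TE2 and -0.05 without TE13. That list was lower by the test with no background subtraction (camera adjusted p = 0.0498), and leukocyte and endothelial markers were higher with Agilent's processed signals (0.0452). With median centring the endoplasmic reticulum stress list (mean relative to all genes 0.33) and the hypoxia list (0.28) were higher, at camera adjusted p = 0.00279 for both.

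**Figure D3:**
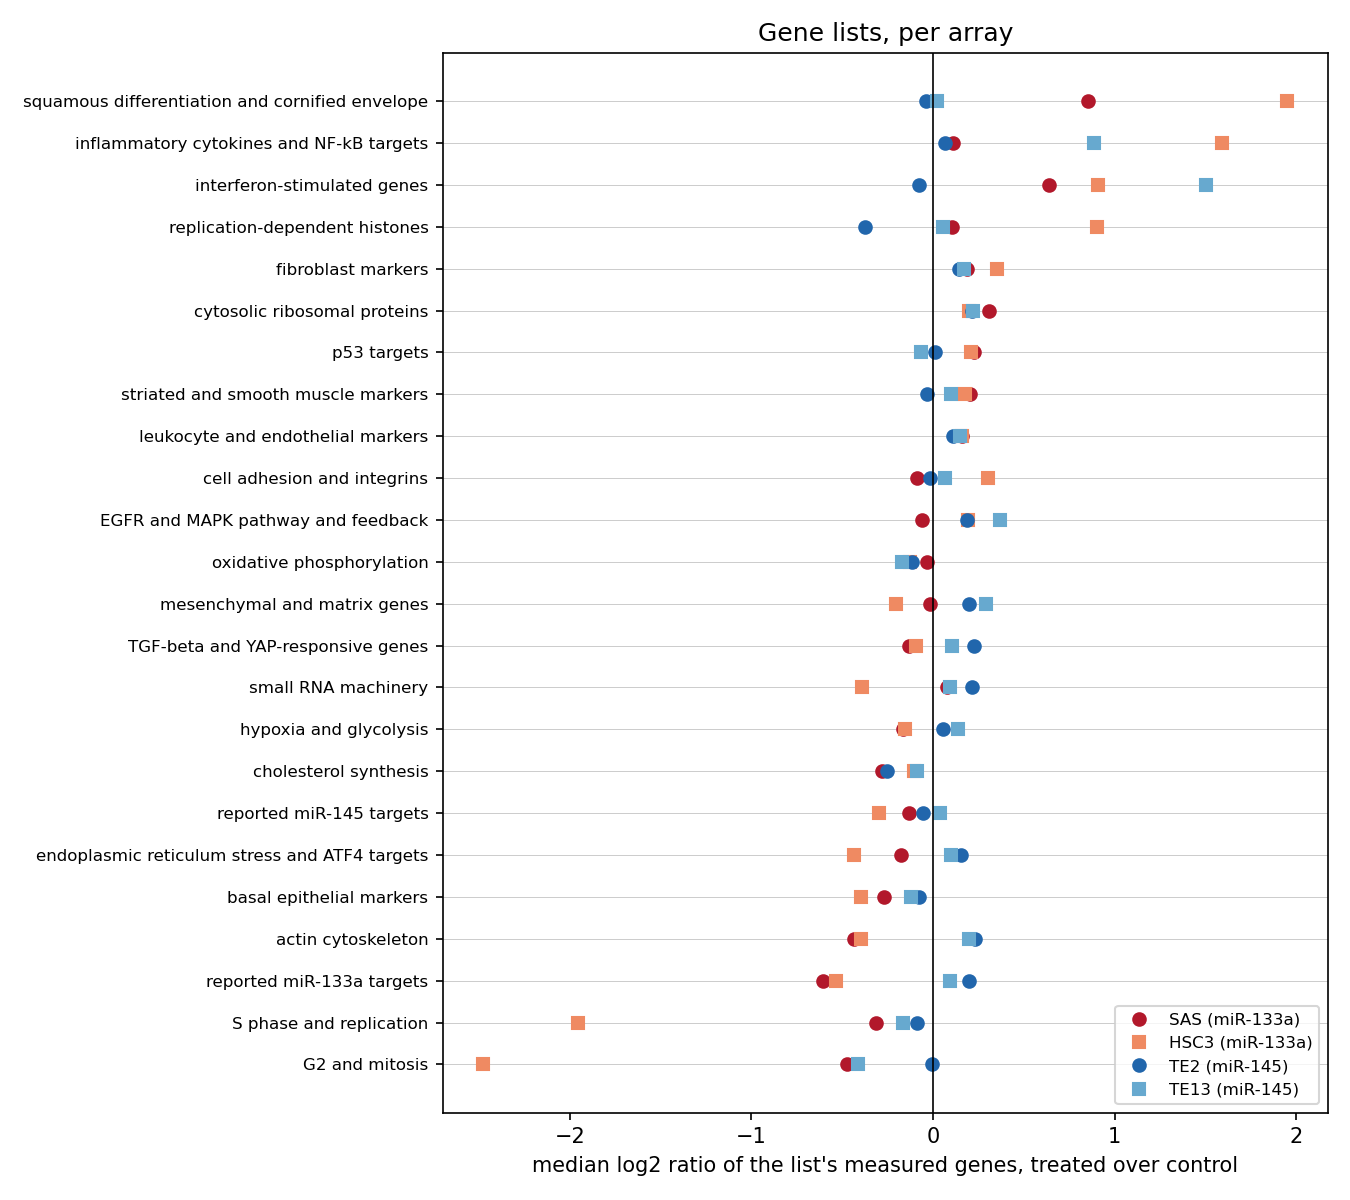
The x axis gives the median log2 ratio (treated over control) of each gene list on each of the 4 arrays, with 1 point per array. Lists are ordered by the sum of their medians in SAS and HSC3. The G2 and mitosis list lies at -2.48 in HSC3 and -0.47 in SAS, interferon-stimulated genes at 1.505 in TE13 and -0.08 in TE2, and ribosomal protein genes between 0.20 and 0.31 on all 4 arrays.

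The difference between the microRNAs asks where they acted unlike each other, with the oral and oesophageal lines confounded with it and a dye effect common to all arrays removed. The squamous differentiation list was higher under miR-133a than under miR-145 by a median of 1.61 (camera adjusted p = 3.10e-10, and adjusted p = 0.593 with an estimated correlation). The actin cytoskeleton list was lower by 0.68 at the median (camera adjusted p = 1.77e-07, and adjusted p = 0.593 with an estimated correlation), with 24 genes lower and 3 higher adjusted over the list alone. The genes set furthest apart were LHFPL6 (-4.69), VIM (-4.05), TPM1 (-3.91), FST (-3.90) and TPM2 (-3.31) on the low side of miR-133a. On the high side were SPRR2D (4.54), SPRR2C (4.43), S100P (4.42), KRT6C (3.87) and KRT80 (3.58). FST, the activin antagonist follistatin, was at -2.02 in SAS and -2.89 in HSC3 but at 1.80 in TE2 and 1.10 in TE13. FSCN1 differed by 0.56 (SE 0.28, limma adjusted p = 0.312).

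With limma 0 genes passed for the difference, with 4874 at an unadjusted p under 0.05, and the 10 genes had an adjusted p of 0.0908. Without SAS or without HSC3, the lone miR-133a array would be tested against the spread of the miR-145 lines, so calls are not given for these fits. The 10 genes were picked as the widest gaps on these same arrays.

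Among the other lists, reported miR-133a targets were lower under miR-133a than under miR-145 (median -0.56, camera adjusted p = 6.28e-05, and adjusted p = 0.593 with an estimated correlation), with 14 lower and 1 higher adjusted over the list alone. G2 and mitosis (median -1.28, camera adjusted p = 6.06e-06) and S phase and replication (-0.98, 4.44e-05) were lower, each at adjusted p = 0.726 with an estimated correlation. Without HSC3 their mean differences relative to all genes were only -0.26 and -0.20, and the G2 and mitosis median of SAS (-0.47) was close to that of TE13 (-0.41). Endoplasmic reticulum stress and ATF4 targets (-0.51, camera adjusted p = 0.00125) and hypoxia and glycolysis (-0.35, 0.0103) were lower and replication-dependent histones (0.93, 0.00135) higher, each at adjusted p = 0.593 with an estimated correlation. The hypoxia list passed no longer with median centring (camera adjusted p = 0.354), at a mean difference relative to all genes of -0.07 against -0.19. That mean difference was -0.13 without SAS and -0.13 without TE13. For the stress list it was -0.21 without HSC3 against -0.46. In the squamous list 13 genes were higher adjusted over the list alone, and in these 5 last lists 0 were.

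The remaining lists did not pass for the difference. The camera adjusted p was 0.795 for reported miR-145 targets, 0.888 for cell adhesion, 0.920 for interferon-stimulated genes, 0.459 for inflammatory cytokines, 0.376 for p53 targets, 0.285 for cholesterol synthesis and 0.175 for basal epithelial markers. It was 0.264 for mesenchymal genes, 0.216 for TGF-beta and YAP, 0.216 for EGFR and MAPK, 0.285 for small RNA machinery, 0.795 for ribosomal proteins and 0.346 for oxidative phosphorylation. It was 0.309 for muscle, 0.795 for fibroblast and 0.795 for leukocyte and endothelial markers. Median or mean differed in sign from the test for reported miR-145 targets, p53 targets and fibroblast markers, and both did for interferon-stimulated genes. That last list depended on 1 line, as its mean difference was -1.004 without TE2 and 0.963 without TE13. Inflammatory cytokines had a mean difference relative to all genes of 0.36. It was 1.10 without SAS and 0.90 without TE13, but -0.39 without HSC3 and -0.19 without TE2. Without HSC3 these values were -0.28 for EGFR and MAPK and -0.40 for TGF-beta and YAP, against -0.21 and -0.34. They were -0.39 for basal, -0.31 for cholesterol synthesis and -0.51 for mesenchymal genes, against -0.43, -0.14 and -0.35. With median centring ribosomal proteins (mean difference relative to all genes 0.348, camera adjusted p = 2.76e-05) and oxidative phosphorylation (0.265, 0.0114) were higher under miR-133a.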

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

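Of the tests in this part, the comparison of HSC3 with SAS ratios widened to the same spread was chosen only after the result was seen. In 8 gene lists the effect of miR-133a differed from that of miR-145 by the test of the difference itself (camera with a preset correlation). None of these calls passed with an estimated correlation, where the lowest adjusted p was 0.593. That run also rests on the 2 residual degrees of freedom of the fit, so it does not tell correlation among genes from low power. The median differences, as miR-133a minus miR-145, were 1.61 log2 units for squamous differentiation and cornified envelope and 0.93 for replication-dependent histones. They were -1.28 for G2 and mitosis, -0.98 for S phase and replication, -0.68 for actin cytoskeleton, -0.56 for reported miR-133a targets, -0.51 for endoplasmic reticulum stress and ATF4 targets and -0.35 for hypoxia and glycolysis. The actin list lay below 0 in both miR-133a lines (-0.43 and -0.39) and above 0 in both miR-145 lines (0.23 and 0.20), and so did the miR-133a targets (-0.61 and -0.53 against 0.20 and 0.09). The histone list lay at 0.11 and 0.90 against -0.37 and 0.05. MicroRNA and cell lines are confounded in all of these differences.

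Among them, the G2 and mitosis list was weighed, because its median was -0.47 in SAS and -2.48 in HSC3, and all 40 members were lower in HSC3. Wider log2 ratios of all genes in HSC3 (SD ratio 1.47) were argued against by a test that widened the SAS ratios by that factor: the median of HSC3 minus widened SAS was -1.72, below the lowest of the random lists matched on intensity (-0.46). Loess normalization was argued against by the gap between the lines, which was -1.97 with loess and -2.07 with median centring, which uses no loess. With Agilent's processed signals the gap was -2.07, but those are LOWESS-normalized too and do not bear on this. A difference between the lines may account for the gap, but with 1 array per line it was not tested, nor were transfection efficiency and growth state, which the labels do not give.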

How the results depend on the processing

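All alternatives were planned, but the use of mean log2 intensity for the trend was chosen after the values were seen. So were the values of lists compared here, each the list's mean log2 ratio minus the mean of all genes. Signal over background and the number of arrays limit these values. Median centring in place of loess left the median of all genes at 0.238 under miR-133a, 0.215 under miR-145 and 0.110 for their difference (0.017, 0.025 and -0.0057 with loess), so directions under it are given relative to all genes. No paired analysis was possible because each array is its own line with its own control. A slide or scan block was not run, as there was 1 slide, and the tests of seed matches and their alternatives (8mer sites, adjustment for 3' UTR length) were not run for lack of 3' UTR sequence. Where an array is left out, the lone array of its microRNA is assumed to vary like the other microRNA's arrays. Over all alternatives, FSCN1 kept its direction and its side of the threshold in 25 values and lost its call in 3, counts stayed within 1.5 times in 86 and moved in 30, and named genes kept direction and side in 589, lost the call in 60, gained it in 20 and reversed in 0. Lists kept both in 772, lost the call in 79, gained it in 27 and reversed in 55. Unless a cause is given, the cause was not tested.

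With only the 2 arrays of that microRNA, 0 genes passed under miR-133a and FSCN1 (-1.56) lost its call (SE 0.19 against 0.20). Leaving out TE2 or TE13 gives the same fit of the miR-133a arrays, so the lost FSCN1 calls are not separate results. That fit has its own spread and fewer residual degrees of freedom. For FSCN1 the SE was smaller, so a wider spread did not cost it the call. What is left for FSCN1 is fewer degrees of freedom and the adjustment over genes. For the other genes, which of these mattered was not tested. Leaving out each array in turn gave 0 to 7522 genes under miR-133a and 0 to 5547 for the difference, and FSCN1 at -1.77 to -1.35. With an estimated correlation in camera 0 list tests passed under miR-133a, 0 under miR-145 and 0 for the difference, against 11, 11 and 8. Correlation alone does not explain all of these losses. The estimated correlation was high for G2 and mitosis (0.98), S phase (0.82), interferon-stimulated genes (0.80) and inflammatory cytokines (0.66). For these lists correlation may account for the loss. Under miR-145 the EGFR and MAPK list went from camera adjusted p = 0.00203 to 0.547, although its estimated correlation was 0.011 against the preset 0.01.

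With median centring 6568 genes passed under miR-133a, 85.9% of them higher. It put 1572 genes higher and 193 lower by 2-fold in both lines under miR-133a, and 171 higher and 7 lower under miR-145, with 6 list tests past under miR-133a and 7 under miR-145. It reversed these lists under miR-133a: TGF-beta and YAP (0.0063), cholesterol synthesis (0.0078), endoplasmic reticulum stress (0.011), fibroblast markers (-0.058), hypoxia (0.21), leukocyte and endothelial markers (-0.061), oxidative phosphorylation (0.40), small RNA machinery (0.00099) and muscle (-0.029). Under miR-145 it reversed S phase (0.053), basal markers (0.12), cell adhesion (0.12), cholesterol synthesis (0.050), fibroblast markers (-0.12), leukocyte and endothelial markers (-0.22) and oxidative phosphorylation (0.13), and for the difference fibroblast markers (0.058) and reported miR-145 targets (0.029).

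Agilent's processed signals and the series table gave, alike, 969 genes higher and 919 lower by 2-fold under miR-133a and 135 higher and 62 lower under miR-145, and the series table gave 7 list tests under miR-145. For the difference, processed signals reversed ribosomal proteins (-0.0017), fibroblast markers (0.31) and interferon-stimulated genes (0.15), and the series table reversed the same (-0.0036, 0.26 and 0.15). Under miR-145 they reversed muscle markers (0.027 with processed signals and 0.025 with the series table). With the mean of all probes 7 list tests passed under miR-145, and fibroblast markers (0.074) and miR-145 targets (0.015) reversed for the difference and miR-133a targets (-0.029) under miR-145. With probes well above background in both channels on all 4 arrays, basal markers (0.0067), miR-133a targets (-0.020) and muscle markers (0.030) reversed under miR-145, and muscle markers under miR-133a (-0.11). For the difference that filter reversed interferon-stimulated genes (0.087), miR-145 targets (0.037) and muscle markers (-0.14). With no filter on dim probes, cell adhesion (0.00027) and fibroblast markers (-0.0073) reversed under miR-145 and fibroblast markers (0.031) for the difference. With no background subtraction, miR-133a targets reversed under miR-145 (-0.0025). By its construction the 1.5-fold rule counted more genes, 1458 higher and 1496 lower under miR-133a and 251 higher and 213 lower under miR-145.

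Leaving out each array in turn reversed lists, in these ranges. Under miR-133a they were -0.20 to 0.48 for cell adhesion, -0.30 to 0.49 for fibroblast markers and -0.27 to 0.049 for mesenchymal genes. Under miR-145 they were -0.13 to 0.026 for basal markers, -0.082 to 0.044 for cell adhesion, -0.17 to 1.80 for interferon-stimulated genes (lowest without TE13) and -0.052 to 0.055 for miR-133a targets. For the difference they were -0.18 to 0.50 for cell adhesion, -0.31 to 0.023 for cholesterol synthesis, -0.44 to 0.36 for fibroblast markers and -0.39 to 1.10 for inflammatory cytokines. They were -1.004 to 0.963 for interferon-stimulated genes and -0.0097 to 0.12 for leukocyte and endothelial markers.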

Other observations

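In this part the tests of a dye effect and of SRF target genes were chosen only after the result was seen. Some genes moved on all 4 arrays by 2-fold or more, beyond what independent lists would share. The 4 lower ones (0.60 expected) were FSCN1, HLTF, TSPAN6 and the unnamed transcript THC2268956, and the 5 higher ones (0.79 expected) were FN1, KRT81, SLC12A7 and the unnamed transcripts AK074181 and ENST00000375377. FN1 was among them by the probe used here, as its other probe had a mean of 0.71 under miR-145, which is less than 2-fold. TSPAN6, a tetraspanin, was at -1.08 in SAS, -1.27 in HSC3, -1.13 in TE2 and -1.19 in TE13. HLTF, a helicase-like transcription factor, was at -1.01, -2.54, -1.07 and -1.11 in the same order. KRT81, a hair keratin, was at 2.98, 3.12, 1.23 and 1.73, and SLC12A7, a potassium chloride cotransporter, at 1.30, 2.49, 1.01 and 1.32. These genes, outside the rule for named genes except FSCN1 and FN1, were chosen after their values were seen, and a dye effect on them was not separable.

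Only FST was lower by 2-fold or more in both miR-133a lines and higher in both miR-145 lines (0.71 genes expected), and 0 genes moved the opposite way (0.67 expected). Some genes of the actin list differed in direction between the microRNAs. CALD1, the actin-binding caldesmon, was at -2.12 under miR-133a and 0.94 under miR-145, CNN2, a calponin, at -2.22 and 0.56, and MYH9, the heavy chain of non-muscle myosin, at -1.36 and 1.13. Others did not, as ACTB, beta-actin, was at 0.73 and 0.92 and TAGLN at 0.87 and 2.13. These genes too were chosen after their values were seen, and under miR-145 none of them passed limma.

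Several genes of the actin list are targets of SRF, the transcription factor of actin and muscle genes, and SRF itself was at -0.31 and -0.11 in SAS and HSC3 and at 1.03 and 1.11 in TE2 and TE13. The hypothesis was that SRF target genes as a set moved in opposite directions, up with miR-145 and down with miR-133a. Over 46 target genes, 21 of them in the actin list, the mean was 0.60 under miR-145 and -0.33 under miR-133a. Over the 25 targets outside the actin list and the genes named by rule, the mean was 0.50 under miR-145 (camera p = 1.74e-08, and p = 0.0244 with an estimated correlation) and 0.11 under miR-133a (camera p = 0.644). The difference had a camera p of 0.0194, and p = 0.121 with an estimated correlation. Those 25 still held SRF, CCN1 and AMOTL2, and over the other 22 the mean was 0.44 under miR-145 (camera p = 2.30e-06, and p = 0.0351 with an estimated correlation), with a camera p of 0.108 for the difference. So the rise of the set with miR-145 may be shared by SRF targets in general, while neither a fall with miR-133a nor, without those 3 genes, a difference was shown outside the actin genes.

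Interferon-stimulated genes lay above 0 in TE13 (40 of 41) and not in TE2 (18 of 41) under miR-145. A higher level in the TE2 control RNA was argued against, as their control-channel level in TE2 minus TE13, relative to all genes, was -1.49 (bootstrap range -2.46 to -1.14). The bootstrap resampled the list's genes, which are not independent replicates, so its range does not cover variation between control RNAs. Genes too dim to measure in TE2 were argued against as well, since 37 of the 41 were well above background in its control channel, with a median of -0.10 in TE2 and 1.49 in TE13. A difference between the lines may account for the pattern, but with 1 array per line it was not tested.

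Ribosomal protein genes lay above 0 on all 4 arrays, at 0.31, 0.20, 0.21 and 0.22. By the rule set beforehand, loess normalization of bright spots remained as a possible explanation. With Agilent's processed signals the medians were 0.11, 0.080, 0.070 and 0.087 and lay above random lists matched on intensity on 2 of 4 arrays. Those signals are LOWESS-normalized too, so the smaller values cannot implicate loess. With median centring, which uses no loess, the medians were 1.39, 1.29, 1.01 and 0.81 and lay above matched lists on 4. The size thus depended on the normalization. Lying above matched lists did not need loess, but median centring leaves any trend of the ratios with intensity in place. The random lists were matched in broad bins of intensity, so such a trend within a bin is not excluded. A dye effect common to the 4 arrays cannot be told apart from an effect of both microRNAs, because no dyes were swapped. The log2 ratios of the 41 single genes correlated across arrays of different microRNAs with a mean r of 0.445 (0.409 to 0.490, across genes, which are not independent replicates), as either would give. No biological explanation was tested.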
